A study of Homo sapiens with 6 samples.

How the data were processed

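Exosomes from the supernatant of 3 parental hepatocellular carcinoma lines (Hep3B, PLC/PRF/5 and Huh7) and of their 3 sorafenib-resistant derivatives were profiled, with 1 array for each line and state. Per the labels' protocols, exosomes were collected by centrifugation, their total RNA was digested with RNase R, an exonuclease that degrades linear RNA, and the remainder was amplified with random primers, labelled with Cy3 and hybridised to the Arraystar Human circRNA Array V2. Resistant lines were grown with 6 µM sorafenib, so that resistance and exposure to the drug coincide in these samples. Whether cultures were independent of one another is not given in the sources used here, and p-values measure only the spread between these arrays.

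The deposited files hold spot intensity values from Agilent Feature Extraction 11.0.1.1 with the protocol GE1_1100_Jul11, per the file headers. The authors' scanner output gives a processed signal intensity that is background-subtracted and carries no normalization between arrays, together with the median intensity of each spot and of its local background. Other deposited columns are spot flags (above background, saturated, outlier) and probe names, and hold no signal unit. The design build is hg19 per the file headers. The submitters' processing notes name limma with no role, so its use by the authors is not known here.

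The array carried 13617 circRNA probes, 70 probes for linear mRNAs with 10 spots each, 60 probes named Negative and 15 named as circRNA controls. The deposited files give the circRNA probes only as the array maker's IDs. No circRNA name, coordinate or host gene was therefore assigned, and the 18 host gene lists fixed beforehand were not tested. The circRNA of the series title was not matched to a probe and no value is given for it. The mRNA probes were named through RefSeq accessions and the gene table of GRCh38.p14, where 70 of 70 matched. Their sequences were not examined, and an mRNA probe can lie in an exon that a circRNA of the same gene also contains.

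The log2 processed signal was scaled by subtracting each array's 75th percentile over non-control probes. Spots of a probe were averaged, and control and outlier spots were left out. Probes well above background on at least 3 of the 6 arrays were tested, which left 13501 circRNAs. limma 3.58.1 in R 4.3.3 was used for a linear model with cell line as a block, eBayes with trend and robust off, and two-sided tests with Benjamini-Hochberg adjustment and a threshold of 0.05. Same-numbered samples carry the same cell line name in the labels, which is the basis of the pairing. Differences between cell lines were tested with the F statistic of the same model. Within a line there is 1 array per state, so those log2 ratios have no replicate check. For the mRNA probes, the spread over the 10 spots of a probe gives a technical error within an array (median SE of a line's log2 ratio 0.028), which does not include the error between cultures or arrays.

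Sets of probes were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The mRNA result and its 9 functional groups were added after the data were seen in part. The groups were written from gene names before the values per gene were examined. The last group holds mRNAs with other functions, and the naming rule was not applied to it. For each of the others the members with the 2 largest and the 2 smallest mean log2 fold changes were named, as the rule set before the data were examined had it for host gene lists. EIF5B, H3-3A, ERGIC2 and MOCOS lie outside that rule and were chosen after their values were seen. The rule for circRNAs took those past the threshold, and, with fewer than 10, those at least 1.5-fold apart in the same direction in all 3 lines. Because the IDs have no names here, it was shortened to 2 IDs higher and 2 lower.

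All 6 arrays were on 1 slide, so a slide effect could not be fitted. The number of arrays limits the precision. On simulated data with 200 changed circRNAs among 13501, the model recovered on average 36.3 of 100 circRNAs changed by 1 on the log2 scale and 93.9 of 100 changed by 2, with 7.1 false calls. The simulated errors were independent between probes and each change was the same in all lines. Errors shared over an array or running with signal were not simulated, so these rates may not hold for the real arrays. Alternatives were quantile, median and cyclic loess scaling, a percentile over detected probes, normexp background correction with an offset of 50, other filters and eBayes settings, no block, and leaving out each pair or array. The planned mean spot intensity is not among the columns, and normexp was run on the median spot and background intensities.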

Results

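Circular RNAs in exosomes were compared between hepatocellular carcinoma lines and derivatives of the same lines that resist sorafenib, a multikinase inhibitor used against this cancer. Hep3B, PLC/PRF/5 and Huh7 are established human liver cancer lines. Each gave 1 parental and 1 resistant sample, and the resistant lines were kept in 6 µM sorafenib. Values are log2 signals scaled to each array's 75th percentile unless stated otherwise, and n = 3 pairs for each mean log2 fold change.

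Signal was present for nearly all circRNA probes. Of 13617 circRNA probes, 13398 were well above background in parental Hep3B and 13104 in resistant Hep3B. The counts were 13574 and 13512 in PLC/PRF/5, and 13521 and 13246 in Huh7. Each resistant array had fewer than its parental array (13497.7 ± 90.3 parental and 13287.3 ± 207 resistant, SD, n = 3), with an exact paired permutation p of 0.25, two-sided, which is the smallest that 3 pairs allow (0.333 adjusted over 4 such comparisons). Probes named Negative were also well above background in many cases, on 41 and 33 of 60 in parental and resistant Hep3B, 45 and 41 in PLC/PRF/5, and 44 and 33 in Huh7. Agilent's own negative control spots passed on at most 1 of 77 spots per array. Signals above the 95th percentile of the probes named Negative were found for 22.0% of circRNA probes in parental Hep3B, 27.4% in resistant Hep3B, 36.4% and 37.7% in PLC/PRF/5, and 25% and 23.2% in Huh7. Before scaling, the median circRNA signal was 71.1 in parental and 37.4 in resistant Hep3B, 72.6 and 59.3 in PLC/PRF/5, and 70.6 and 39.3 in Huh7.

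**Figure D1:**
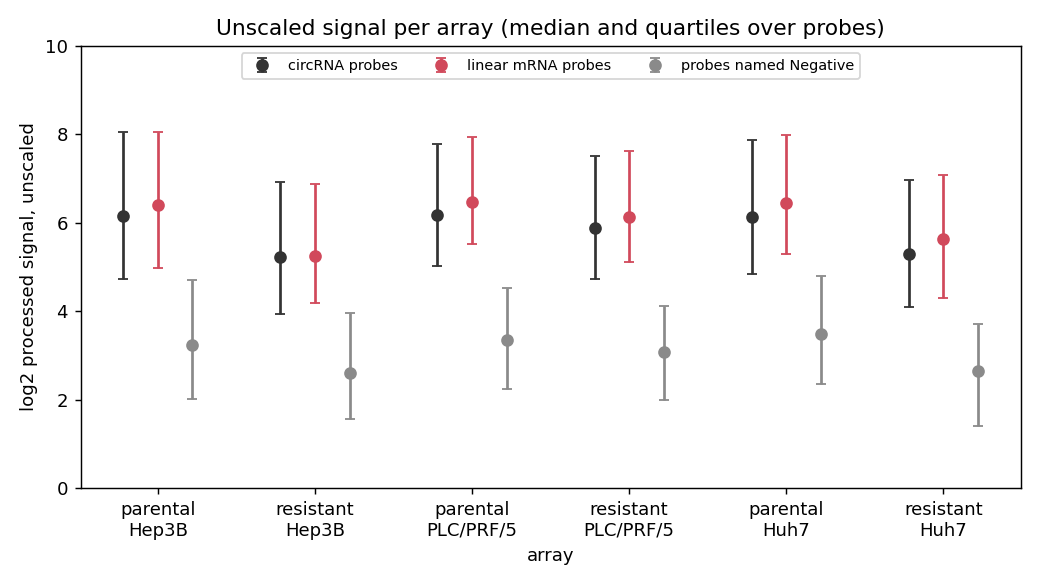
Unscaled log2 processed signal (vertical axis) on each of the 6 arrays (horizontal axis), with points at the median and bars from the lower to the upper quartile over the circRNA probes, linear mRNA probes and probes named Negative. The circRNA median is 6.15 in parental and 5.23 in resistant Hep3B, 6.18 and 5.89 in PLC/PRF/5, and 6.14 and 5.30 in Huh7.

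**Figure D2:**
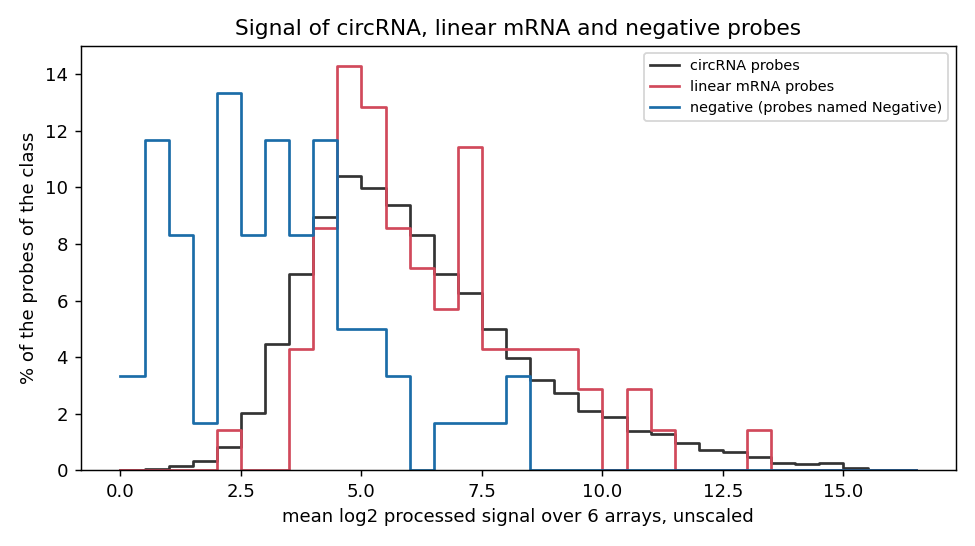
Percent of the probes of each class (vertical axis) by mean unscaled log2 processed signal over the 6 arrays (horizontal axis), for circRNA probes, linear mRNA probes and probes named Negative. The probes named Negative lie further to the left than the circRNA probes, and the distributions of these classes overlap widely.

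The first comparison asked which circRNAs differ between resistant and parental exosomes across the 3 lines. No circRNA of 13501 passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), and the smallest adjusted p was 0.360. At an unadjusted p under 0.05 there were 1803, of which 1163 were higher and 640 lower in resistant exosomes, where chance gives 675.05. That split followed the scaling, with 828 higher and 878 lower after quantile normalization and 765 higher and 1046 lower after median centring. With normexp background correction 3261 circRNAs passed, and with the arrays scaled before the normexp offset was added, 0 passed. Without the PLC/PRF/5 pair 4 passed. The count at an unadjusted p under 0.05 depended on the pairs used, with 562 without Huh7, 2262 without PLC/PRF/5 and 1943 without Hep3B.

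The largest mean differences shared by the lines belonged to circRNAs that did not pass the test. At least 1.5-fold in the same direction in all 3 lines, and well above background on all 6 arrays, were 31 circRNAs, 26 of them higher and 5 lower, where independent lines would give 3.78 higher and 0.361 lower. Log2 ratios of Hep3B and Huh7 were correlated even over the probes named Negative (r = 0.497). An effect on whole arrays could therefore also give more than independent lines would. The probe ASCRP3007103 had a mean log2 fold change of 2.27 (SE 0.376, adjusted p = 0.360), with log2 ratios of 1.86 in Hep3B, 3.42 in PLC/PRF/5 and 1.54 in Huh7. ASCRP3000384 had 2.22 (SE 0.364, adjusted p = 0.360), with nearly the same log2 ratios of 1.79, 3.33 and 1.54. Whether these probes detect separate circRNAs is not known here. On the lower side, ASCRP3011306 had -0.89 (SE 0.145) and ASCRP3013193 had -0.85 (SE 0.135), both with an adjusted p of 0.360.

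Within each line, the resistant and parental arrays were set side by side with no replicate check. In Hep3B, 506 circRNAs were at least 2-fold higher and 310 at least 2-fold lower in resistant exosomes, of 13048 well above background on both arrays. In PLC/PRF/5 the counts were 112 and 37 of 13472, and in Huh7 136 and 13 of 13229. Quantile normalization gave 216 higher and 213 lower in Hep3B, and median centring gave 263 higher and 538 lower there. Well above background in the parental sample alone were 331 circRNAs in Hep3B, 28 in PLC/PRF/5 and 254 in Huh7, and in the resistant sample alone 43, 1 and 4. The call rests on unscaled signal, which was lower on each resistant array, where fewer probes named Negative passed too. Loss of single circRNAs and a dimmer array cannot be told apart in these last counts.

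The lines were then compared for a shared direction. The sign of the log2 ratio was the same in all 3 lines for 5580 circRNAs (41.3%), 3085 of them higher and 2495 lower, where independent signs give 25%. Turning the direction of a single line gave 24.3% for Hep3B, 24.4% for PLC/PRF/5 and 9.98% for Huh7, and 3 lines are too few for a test of this share. Across circRNAs, which are not independent replicates, the log2 ratios of Hep3B and Huh7 had a Pearson r of 0.40 (Spearman 0.42), those of PLC/PRF/5 and Huh7 0.33 (0.41), and those of Hep3B and PLC/PRF/5 -0.023 (0.050). In Hep3B the median log2 ratio ran from 0.50 among the dimmest circRNAs to -0.46 among the brightest, in Huh7 from 0.16 to -0.16, and in PLC/PRF/5 from -0.069 to -0.11.

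**Figure D3:**
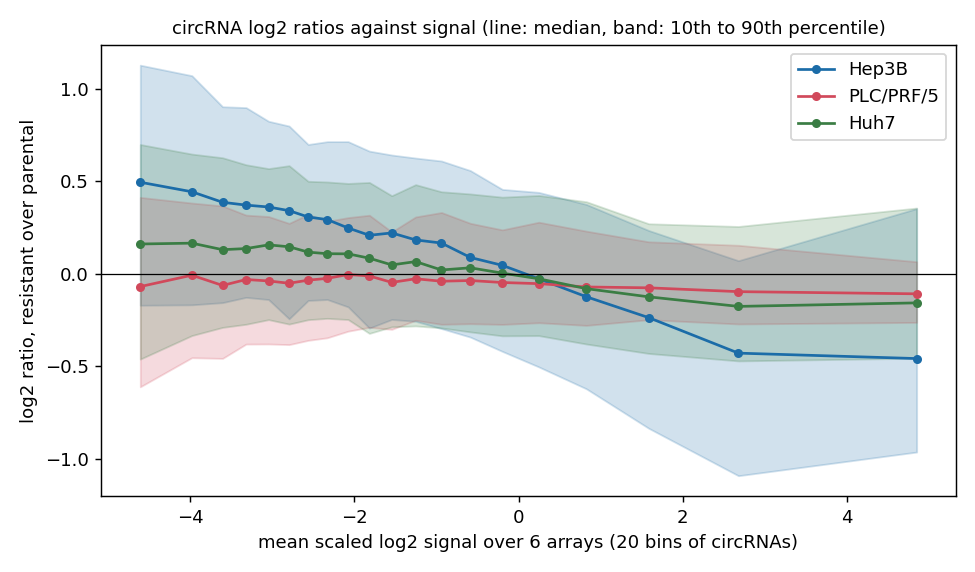
Log2 ratio of resistant over parental signal (vertical axis) against the mean scaled log2 signal over 6 arrays (horizontal axis) for circRNAs in 20 bins of equal size, with lines at the median and bands from the 10th to the 90th percentile for each cell line. The Hep3B median runs from 0.50 in the dimmest bin to -0.46 in the brightest.

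Differences between the cell lines were fitted in the same model, to set their size beside that of resistance. No circRNA passed (limma F test, smallest adjusted p = 0.117), and 2566 had an unadjusted p under 0.05. At least 2-fold apart were 691 circRNAs between Hep3B and PLC/PRF/5, 304 between Hep3B and Huh7, and 280 between PLC/PRF/5 and Huh7. These counts compare the mean of the parental and resistant arrays of each line, over all tested circRNAs. The counts within lines compare single arrays, over circRNAs well above background on both, so the sizes are not like for like. Pearson r across circRNAs was 0.975 to 0.986 between arrays of different lines, and 0.977, 0.991 and 0.989 between the parental and resistant arrays of Hep3B, PLC/PRF/5 and Huh7. With normexp background correction 38 circRNAs passed.

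The linear mRNA probes were the part of the array that could be named. None of the 70 passed, either adjusted over the list alone (smallest adjusted p 0.562) or with all probes (0.361), and 5 had an unadjusted p under 0.05. Signs were the same in all 3 lines for 9 higher and 13 lower mRNAs and mixed for 48. In Hep3B, 3 mRNAs were at least 2-fold higher and 1 at least 2-fold lower in resistant exosomes. In PLC/PRF/5 and Huh7, 0 reached 2-fold either way. Many of the named probes were dim. RACK1, ERGIC2, EIF5B, CD69 and LMO2 were below the 95th percentile of the probes named Negative on every array. So were EXO1, ABRAXAS1, DNTTIP2, SMARCAD1, BAZ1A, SPP1, SAA4 and CPS1. The same held for PPIP5K2, PLA2G4A, LOX, COL13A1 and NMI.

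Among 19 mRNAs of the cell cycle, DNA replication and repair, 9 were higher and 10 lower by mean log2 fold change and 0 passed. RAD54B, a helicase-like protein of homologous recombination, had log2 ratios of 1.76 in Hep3B, -0.54 in PLC/PRF/5 and 0.28 in Huh7 (mean 0.50, SE 0.429). EXO1, an exonuclease of mismatch repair, had 0.67, -0.28 and 0.36. DTL, a substrate receptor of a ubiquitin ligase active in S phase, had -0.40, -0.66 and -0.090 (mean -0.38, SE 0.154, adjusted p = 0.607 over the list), and its mean was -0.16 with normexp. ABRAXAS1, which acts with BRCA1 in repair, had 0.035, -0.67 and -0.41, and its mean of -0.35 became 0.18 with normexp.

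Among 8 mRNAs of ribosome and translation, 5 were higher and 3 lower by mean and 0 passed. RACK1, a scaffold on the small ribosomal subunit, had log2 ratios of 0.37 in Hep3B, 0.28 in PLC/PRF/5 and 0.43 in Huh7 (mean 0.36, SE 0.119, adjusted p = 0.562 over the list). Its mean was 0.22 after quantile normalization and 0.20 after cyclic loess scaling. RPS18, a protein of the same subunit, had 0.34, 0.25 and 0.46 (mean 0.35, SE 0.122, adjusted p = 0.562). RPL10, of the large subunit, had -0.68, 0.16 and -0.39. DNTTIP2 had 0.54, -0.31 and -0.44, and EIF5B, a translation initiation factor, had 0.88, -0.51 and 0.19. RACK1, DNTTIP2 and EIF5B had unscaled signals below the 95th percentile of the probes named Negative on every array. For RACK1 they were 27.1 parental and 15.9 resistant in Hep3B, 34.6 and 34.7 in PLC/PRF/5, and 32.2 and 23.2 in Huh7. CircRNAs near its mean scaled signal had a median log2 ratio of 0.34 in Hep3B, -0.051 in PLC/PRF/5 and 0.15 in Huh7.

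Among 6 mRNAs of the cytoskeleton and its regulators, 3 were higher and 3 lower by mean and 0 passed. PFN1, the actin-binding protein profilin, had log2 ratios of -0.67, -0.26 and -0.30 in Hep3B, PLC/PRF/5 and Huh7 (mean -0.41, SE 0.141, adjusted p = 0.562 over the list). RND3 had -0.51, -0.18 and -0.37 (mean -0.35, SE 0.130, adjusted p = 0.562). DYNLL1, a dynein light chain, had 1.24, -0.21 and -0.088, and ACTG1, a cytoplasmic actin, had -0.12, 0.18 and 0.30. The mean of PFN1 was -0.18 after cyclic loess scaling, and that of RND3 was -0.35 there. The group as a whole did not pass (camera adjusted p = 0.270, and adjusted p = 0.886 with an estimated correlation).

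Among 8 mRNAs of chromatin and transcription, 3 were higher and 5 lower by mean and 0 passed. SMARCAD1, a chromatin remodeller, had log2 ratios of 0.84 in Hep3B, -0.21 in PLC/PRF/5 and 0.056 in Huh7. BAZ1A, a subunit of remodelling complexes, had 0.13, 0.22 and 0.22. ZNF195, a zinc finger protein, had -0.17, -0.17 and -0.35 (mean -0.23, and -0.10 after quantile normalization). POLR2A, the catalytic subunit of the polymerase that makes mRNA, had -0.13, -0.20 and -0.35, and its mean of -0.23 became 0.011 after quantile normalization. H3-3A, which encodes a replacement histone, had -1.27, 0.19 and 0.70.

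Among 4 mRNAs of liver-secreted proteins and the urea cycle, 3 were higher and 1 lower by mean and 0 passed. SPP1, the secreted phosphoprotein osteopontin, had log2 ratios of 1.003 in Hep3B, -0.23 in PLC/PRF/5 and 0.25 in Huh7. Its unscaled signal in Hep3B was 40.6 parental and 37.0 resistant, so it was not higher before scaling. SAA4, a serum amyloid protein, had 0.13, 0.30 and 0.20. SERPIND1, a plasma inhibitor of thrombin, had -0.41, -0.023 and -0.59 (mean -0.34, and -0.11 after quantile normalization). CPS1, the first enzyme of the urea cycle and the sole mRNA probe from the fixed list of hepatocyte identity, had 0.50, -0.20 and -0.084, and its mean of 0.074 became -0.087 after quantile normalization.

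Among 9 mRNAs of metabolic and mitochondrial enzymes, 7 were higher and 2 lower by mean and 0 passed. PPIP5K2, an inositol phosphate kinase, had log2 ratios of 0.79, 0.027 and 0.28 in Hep3B, PLC/PRF/5 and Huh7. GAPDH, a glycolytic enzyme, had 0.60, -0.29 and 0.38. MTX1, a protein of the mitochondrial outer membrane, had -0.37, -0.13 and -0.12, and its mean of -0.21 became -0.027 after quantile normalization. The phospholipase PLA2G4A had 0.20, -0.24 and -0.015. MOCOS, a molybdenum cofactor enzyme, had 0.37, -0.40 and 0.46.

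Of 3 mRNAs of collagen and its cross-linking, LOX, a lysyl oxidase that cross-links collagen, had log2 ratios of -0.94, 0.10 and -0.56 in Hep3B, PLC/PRF/5 and Huh7. LOXL2, a related enzyme, had -0.050, -0.13 and -0.24, and the collagen COL13A1 had 0.50, -0.068 and 0.25, with 0 of 3 past the test. Of 6 mRNAs known from blood and immune cells, 0 passed. LMO2 had 0.62, -0.10 and 0.25, RHOH 0.097, 0.13 and 0.17, CD69 0.20, 0.16 and -0.58, and NMI 0.24, -0.63 and -0.35. Of 7 mRNAs with other functions, 5 were higher and 2 lower by mean and 0 passed. Among them ERGIC2, a protein of the early secretory pathway, had 0.42, 0.33 and 0.38 (mean 0.37, SE 0.117, adjusted p = 0.562 over the list), and its mean was 0.24 after cyclic loess scaling.

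**Figure D4:**
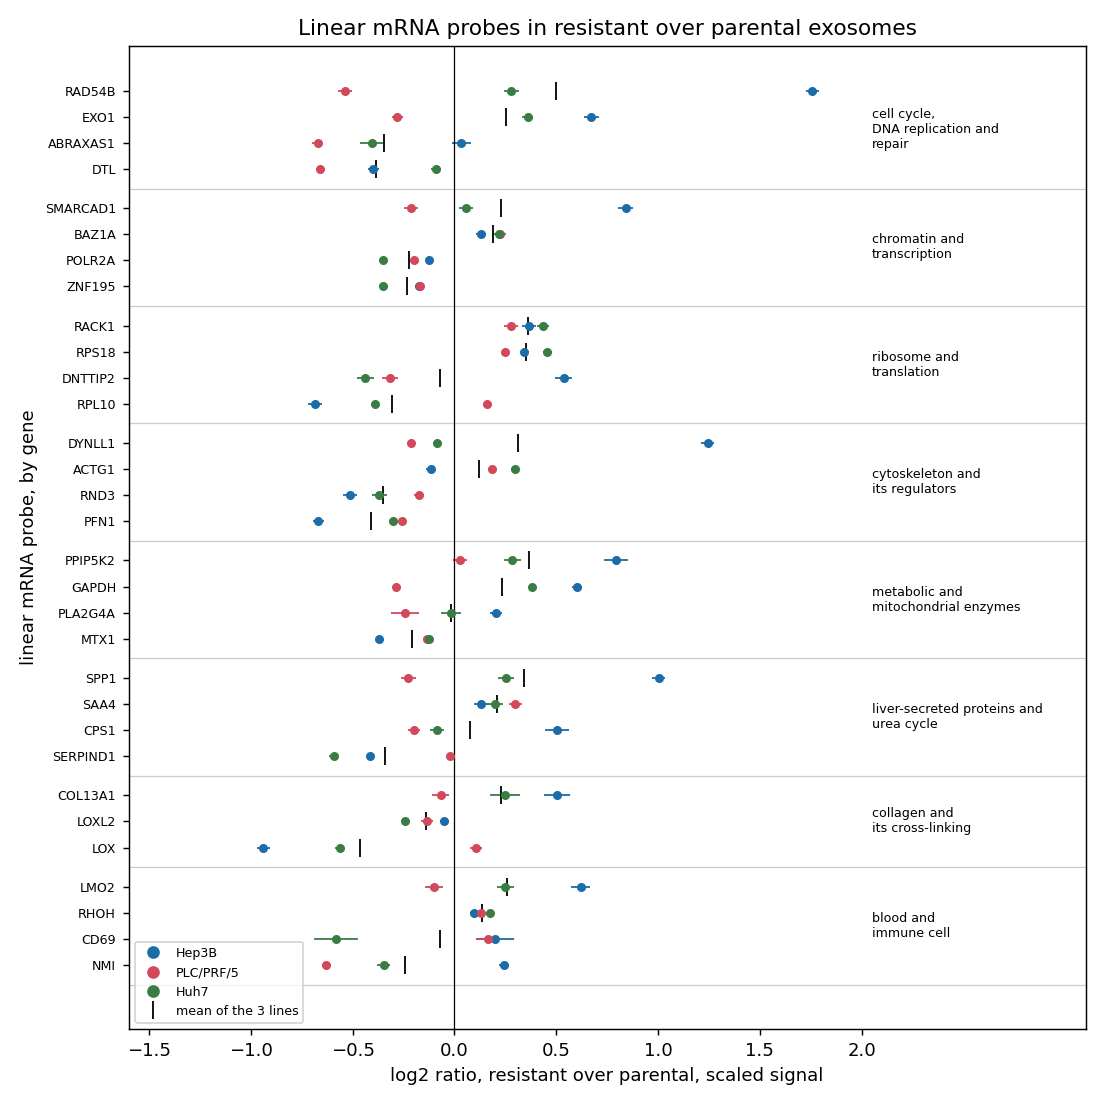
Log2 ratio of resistant over parental scaled signal (horizontal axis) for named linear mRNA probes by functional group (vertical axis), with a point for each cell line, bars for the standard error over the spots of a probe within these arrays, and a black tick at the mean of the 3 lines. RACK1 and RPS18 lie to the right and PFN1 and RND3 to the left of 0 in all 3 lines at this scaling, none past the adjusted threshold, and RAD54B runs from -0.54 in PLC/PRF/5 to 1.76 in Hep3B.

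Classes of probes were compared with the circRNA probes as sets. The linear mRNA probes had a median log2 fold change of 0.033 beside 0.052 for the circRNAs (camera adjusted p = 0.555, and adjusted p = 0.886 with an estimated correlation). The 15 circRNA control probes had a median of -0.086 and the 41 tested probes named Negative a median of 0.14, both with a camera adjusted p of 0.150 and adjusted p = 0.886 with an estimated correlation.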

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

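The tests of circRNA loss and of the count past the threshold were chosen after the result was seen; the other tests below were chosen before their results were seen.

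Among 35 named mRNAs, 18 had log2 ratios that went opposite ways in different lines, beyond 2 standard errors over the spots of a probe. The flag is easily met, since spot error leaves out the error between cultures and arrays. Of all 70 mRNAs, 68 in Hep3B, 61 in PLC/PRF/5 and 61 in Huh7 lay beyond 2 such errors, and 48 had mixed signs. Hep3B also had the widest spread of circRNA log2 ratios (SD 0.578, beside 0.305 in PLC/PRF/5 and 0.359 in Huh7). The difference between lines was not tested, since each line has 1 pair of arrays. The largest ratio minus the smallest was 2.30 for RAD54B, 1.97 for H3-3A, 1.46 for DYNLL1, 1.39 for EIF5B, 1.23 for SPP1, 1.05 for SMARCAD1 and 1.04 for LOX, and in each of these Hep3B held an extreme value. It was 0.97 for DNTTIP2, 0.95 for EXO1, 0.89 for GAPDH, 0.87 for NMI, 0.86 for MOCOS and 0.85 for RPL10. It was 0.78 for CD69, 0.72 for LMO2, 0.70 for CPS1, 0.44 for PLA2G4A and 0.41 for ACTG1. Signal outside the main measurement was seen in the probes named Negative, of which at least 55% were well above background on every array, and in Agilent's E1A probes, whose highest log2 median signal on an array was 7.61. Whether E1A RNA was added is not given in the sources used here.

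Unscaled signal was lower on all 3 resistant arrays, with a median log2 difference for circRNA probes of -0.98 in Hep3B, -0.32 in PLC/PRF/5 and -0.86 in Huh7. The bright corner spots, which do not depend on the sample, were also dimmer on each resistant array (-0.36 in Hep3B, -0.31 in PLC/PRF/5 and -0.25 in Huh7). Some dimming that does not come from the sample thus went with state in all 3 lines. It was at most 36.8% of the circRNA difference in Hep3B and Huh7, which is what less labelled RNA on the resistant arrays would give. In PLC/PRF/5 it was 96.4%. Other probes fell too, the linear mRNA probes by at least 95.9% of the circRNA difference in every line. The probes named Negative fell by 61.3%, 69.8% and 99.7% of it in Hep3B, PLC/PRF/5 and Huh7. For the E1A probes the values were 53.3%, 34.0% and 71.7%. The circRNA control probes, whose targets are not given in the sources used here, differed by more than the circRNA probes (-1.24, -0.39 and -0.98). These values cannot show whether circRNA alone was lost. The mRNA probes can share exons with circRNAs, and the targets of the probes named Negative are not given in the sources used here. The probes named Negative and the E1A probes also fell by less. A loss of circRNA thus stays open, alone or with other RNA. Resistance, sorafenib exposure and the amount of RNA per preparation coincide in this design, and a lower yield from resistant cells stays open as an untested biological difference.

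The log2 ratios of Huh7 correlated with those of Hep3B (r = 0.40) and of PLC/PRF/5 (r = 0.33), while Hep3B and PLC/PRF/5 had r = -0.023. A trend with signal intensity is argued against as the whole cause, since after it was removed r was 0.333 for Hep3B with Huh7, 0.333 for PLC/PRF/5 with Huh7 and -0.035 for Hep3B with PLC/PRF/5. The 60 probes named Negative had r = 0.497 for Hep3B with Huh7 (95% interval over probes 0.278 to 0.666), 0.23 for PLC/PRF/5 with Huh7 and 0.20 for Hep3B with PLC/PRF/5. What these probes target is not given in the sources used here, so for Hep3B and Huh7 an effect on the whole array and a shared response to resistance cannot be told apart.

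Signals were nearly alike on all 6 arrays (r of 0.975 or more between different lines). Few very bright probes do not account for it, since the lowest correlation was 0.955 with ranks or without the brightest 10%. The probes named Negative correlated at a mean r of 0.967 between lines, but their target is not given in the sources used here, so hybridisation that does not need the target and a circRNA content shared by the lines cannot be told apart.

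For the count of circRNAs, 10 splits of the 6 arrays are too few for a share under 0.05. In the fit without the block, the real split gave 0 past the threshold, as did all 10 splits (highest other 0), and 1130 at an unadjusted p under 0.05. At least as many unadjusted came from 3 splits, the real one among them. The highest other was 2028, with both Hep3B arrays and parental Huh7 on the same side. In the blocked fit the real directions gave 0 past the threshold and 1803 unadjusted. Turning Hep3B, PLC/PRF/5 or Huh7 gave 0, 1 and 0 past the threshold and 413, 715 and 46 unadjusted.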

How the results depend on the processing

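Cyclic loess scaling, the restriction to circRNAs above the 95th percentile of the probes named Negative, the further normexp settings, and the mRNA values without single arrays were chosen after seeing the data; the other settings were fixed before the data were examined. The count of 0 circRNAs past the threshold was the same under every setting run except normexp with its offset and the fit without the PLC/PRF/5 pair. On simulated data of this size, 36.3 of 100 circRNAs changed by 1 on the log2 scale were recovered. Smaller changes and errors shared over an array were not simulated. For single mRNAs, 655 values under other settings kept their sign and 45 turned, none past the threshold. Where no cause is given below, the cause was not tested.

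Normexp background correction gave 3261 circRNAs past the threshold, 2628 of them higher and 633 lower in resistant exosomes, and 6553 at an unadjusted p under 0.05. The calls that were higher had a median scaled log2 signal of -3.59 and those that were lower 3.15, beside -1.68 for all tested. Normexp without the offset gave 0 past the threshold (1973 unadjusted), and with the arrays scaled to a common level before the offset it gave 0 (1987 unadjusted). The offset of 50, added while resistant arrays were dimmer, is thus what produced these calls. The same setting moved the median log2 fold change of all circRNAs from 0.052 to 0.26. Under it 38 circRNAs differed between lines (689 unadjusted beside 2566), the sign was shared for 69.9%, and Pearson r was 0.25 for Hep3B with PLC/PRF/5 and 0.79 for Hep3B with Huh7. Counts at least 2-fold apart were 130 higher and 366 lower in Hep3B, where the main setting has 506 higher and 310 lower, 66 higher and 15 lower in PLC/PRF/5, and 29 higher and 0 lower in Huh7. As the median log2 fold change minus that of the circRNAs, the circRNA control probes stood at -0.22 and the probes named Negative at 0.19, both past the threshold (adjusted p = 0.505 and 0.864 with an estimated correlation). Turned in sign were PLA2G4A (0.40), NMI (0.073), ABRAXAS1 (0.18), CD69 (0.45) and DNTTIP2 (0.23).

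Leaving cell line out of the fit (no replicate block) gave 1130 at an unadjusted p under 0.05 in place of 1803 and changed no call. The plain paired test with at least 1.5-fold gave 120. Of the unadjusted counts, 64.5% were higher in resistant exosomes in the main setting, 48.5% after quantile, 42.2% after median, 46.2% after cyclic loess scaling and 82.6% with normexp.

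Quantile normalization gave a shared sign for 38.7%, 216 higher in Hep3B and 26 lower in Huh7, and turned CPS1 (-0.087), POLR2A (0.011), EIF5B (-0.021) and H3-3A (0.096). Cyclic loess gave 38.6%, 288 and 28, turned CPS1 (-0.083), EIF5B (-0.0049) and H3-3A (0.092), and put the probes named Negative at -0.0020 in place of 0.09. Median centring gave 42.9%, with 263 higher and 538 lower in Hep3B, and CPS1 at -0.012. With no filter on dim probes, the probes named Negative stood at 0.18, past the threshold (adjusted p = 0.892 with an estimated correlation), and 33 circRNAs were lower in Huh7.

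With the 2843 circRNAs above the 95th percentile of the probes named Negative on every array, 553 had an unadjusted p under 0.05 (207 between lines) and 56.2% shared a sign. At least 2-fold apart were 47 higher and 219 lower in Hep3B, against the main direction, 31 higher and 10 lower in PLC/PRF/5, and 28 higher and 0 lower in Huh7; fewer circRNAs entered these counts. Against these brighter circRNAs the linear mRNA probes stood at 0.20 in place of -0.019 (camera adjusted p = 1.2e-05) and the probes named Negative at 0.31 (3.2e-12), both past the threshold, though not with an estimated correlation (adjusted p = 0.373 for each). These shifts say nothing of the classes themselves, since the ratios fall with signal in Hep3B and Huh7 and the circRNAs alone were limited to bright probes. The circRNA control probes stood at 0.082 in place of -0.14 and did not pass (adjusted p = 0.467). With a 1.5-fold limit the counts were 2132 higher and 982 lower in Hep3B, 360 and 306 in PLC/PRF/5, and 946 and 243 in Huh7. With 4-fold they were 70 and 21, 16 and 2, and 14 and 0. By the positive and significant call, detection was higher, at 13607 and 13603 in parental and resistant Hep3B, 13613 and 13613 in PLC/PRF/5, and 13617 and 13600 in Huh7.

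Leaving out each pair gave 0 to 4 circRNAs past the threshold, the 4 without the PLC/PRF/5 pair, and leaving out single arrays in the fit with no replicate block gave 0 throughout. Unadjusted counts ran from 432 to 2320 over all of these, with 562 without the Huh7 pair, 2262 without PLC/PRF/5 and 1943 without Hep3B, and without single arrays 609 (parental Hep3B), 757 (resistant Hep3B), 2320 (parental PLC/PRF/5), 955 (resistant PLC/PRF/5), 432 (parental Huh7) and 512 (resistant Huh7). Between lines, 0 to 1 passed and 1530 to 3409 were under 0.05 unadjusted. With a pair left out, the shared sign ran from 51.3% to 65.7%, where independent signs of 2 lines give 50%, and the probes named Negative from 0.021 to 0.15, past the threshold without the Huh7 pair (camera adjusted p = 0.0078, and adjusted p = 0.914 with an estimated correlation). In the fit with no replicate block they also passed without resistant PLC/PRF/5 (0.15, adjusted p = 0.0259), parental Huh7 (0.19, adjusted p = 0.0025) and resistant Huh7 (0.11, adjusted p = 0.0266), and with an estimated correlation in none of these (adjusted p = 0.860, 0.9001 and 0.893). Without each pair, values ran from -0.21 to 0.18 for CD69, -0.14 to 0.21 for CPS1, -0.38 to 0.11 for DNTTIP2, -0.15 to 0.58 for DYNLL1, -0.16 to 0.53 for EIF5B, -0.54 to 0.45 for H3-3A, -0.015 to 0.41 for MOCOS, -0.13 to 0.094 for PLA2G4A, -0.13 to 1.02 for RAD54B and -0.079 to 0.45 for SMARCAD1. Without single arrays, the sign turned for COL13A1 (-0.0040), CPS1 (-0.14), EIF5B (-0.28) and H3-3A (0.18) without parental Hep3B, and for RAD54B (-0.042), CD69 (0.065), DYNLL1 (-0.11), H3-3A (0.14) and MOCOS (-0.23) without resistant Hep3B. It turned for PLA2G4A (0.036), NMI (0.052), ABRAXAS1 (0.057), CD69 (0.18) and DNTTIP2 (0.14) without parental PLC/PRF/5, and for PLA2G4A (0.039) and CPS1 (-0.011) without resistant PLC/PRF/5. It turned for MOCOS (-0.24) without parental Huh7, and for PLA2G4A (6.4e-05), CD69 (0.16), DNTTIP2 (0.050) and ACTG1 (-0.00070) without resistant Huh7. Over all of these, ABRAXAS1 ran from -0.81 to 0.057, ACTG1 from -0.00070 to 0.24, COL13A1 from -0.0040 to 0.43 and NMI from -0.53 to 0.052.

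Host gene lists, with their alternatives including 1 value per host gene, were not run because no table used here pairs probes with host genes. A slide block was not run because all arrays were on 1 slide.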

Other observations

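The test of linear RNA was chosen before its result was seen, the tests of mRNAs between lines were added after the data were seen, and the 4 circRNAs were singled out after the fit without PLC/PRF/5 was seen.

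Some mRNAs stood apart in a cell line, though none of 70 passed (limma F test, smallest adjusted p 0.066 over the list alone, with 15 at an unadjusted p under 0.05). PRMT1, an arginine methyltransferase, was 1.07 on the log2 scale above the mean of the other lines in PLC/PRF/5 exosomes (adjusted p = 0.066). ABRAXAS1 stood at 0.97 in PLC/PRF/5 and -1.10 in Hep3B, and ZZZ3, a subunit of a histone acetyltransferase complex, at 0.67 and -0.94, both with an adjusted p of 0.066. SAA4 stood at -0.68 in Hep3B and 0.57 in Huh7 (adjusted p = 0.093). PRMT1, ABRAXAS1, ZZZ3 and SAA4 were dim, with unscaled signals below the 95th percentile of the probes named Negative on every array. Signals of PRMT1 ran from 9.42 to 41.1, where that percentile ran from 95.7 to 329. Whether dim probes as a whole differed between the lines in this way was not tested.

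Without the PLC/PRF/5 pair, 4 circRNAs passed (limma, adjusted p from 0.0273 to 0.0284). Their log2 ratios of resistant over parental signal were 2.84 to 4.29 in Hep3B and 2.75 to 3.47 in Huh7, and -1.81 to -0.73 in PLC/PRF/5. The difference between lines was not tested, and the circRNAs have no names here.

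A hypothesis was that linear RNA left after RNase R digestion moved with resistance. The linear mRNA probes differed from the circRNA probes by a mean of -0.024 in median log2 ratio, with 0.042 in Hep3B, -0.078 in PLC/PRF/5 and -0.035 in Huh7. The mean was smaller in size than the SD of these 3 line values (0.060), which did not share a sign. Over the set, camera with an estimated correlation gave p = 0.637 (adjusted p = 0.886). The hypothesis stays open.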
